A study of Mus musculus with 6 samples.

How the data were processed

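Total RNA of mouse lung was measured on Affymetrix whole-genome mouse arrays, a short-oligonucleotide platform on which a set of probes against the 3' part of a transcript (a probe set) gives 1 value. The series held 6 arrays, 3 labelled Carm1 knockout and 3 labelled wild type, with 1 array per labelled sample. RNA was isolated with a Qiagen column kit and converted into biotin-labelled cRNA by the array maker's procedure, per the labels' protocols. The deposited values were intensity values on a linear scale, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. In these values the mean after trimming 2% of the probe sets at each end was 500 on every array, so each array had been scaled to 1 common level and not otherwise matched to the others. Detection calls, background settings and hybridisation dates were not used here. The number of arrays limits the precision of every value below.

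The groups came from the sample descriptions. The knockout labels spell the gene both as Carm1 and as CRAM1, and both spellings were read as Carm1. The study's design text gives embryonic day 18.5 for both genotypes, as do the sample labels of the knockouts, whereas the sample labels of the wild types say neonatal. The labels do not say whether the samples came from separate fetuses or litters, so the p-values measure the spread between these samples only.

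The table held 45101 probe sets. Gene symbols were taken from the platform annotation and updated through the gene ID in a RefSeq gene table of the mouse assembly GRCm38.p6, which was used for names, chromosomes and gene order and not for coordinates. Of the probe sets, 34945 had 1 symbol, 932 had several and 9160 were not named here, and 34754 of the symbols were found through the gene ID. No probe set with several symbols was named. After 64 control probe sets were left out, probe sets whose mean log2 value over all 6 arrays lay above the 40th percentile (a signal of 59.7) were tested, 27022 in all, of which 23424 had 1 symbol and stood for 12947 genes. No value was 0 or below, so log2 was taken with no pseudocount. Because the trimmed means were equal, no further normalization was applied in the main setting, as fixed beforehand.

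Each probe set was tested with limma 3.58.1 (lmFit, then eBayes with an intensity trend, two-sided) in R 4.3.3 with version 1.17.8 of data.table, knockout minus wild type, and p was adjusted by the method of Benjamini and Hochberg over the tested probe sets with a threshold of 0.05. A second, descriptive count took an unadjusted p under 0.01 with a difference of at least 1 log2 unit. Single values were also compared by an exact two-sided permutation test, for which 3 against 3 arrays cannot give a p under 0.1. Means are given with the SD over 3 arrays on the linear signal scale, and fold values are ratios of geometric means from the fit.

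The lists of marker and pathway genes, 35 in all, were fixed before the data were examined, as were the tests, the filter, the alternatives and the rule for named genes. Lists with at least 5 measured members, 32 of them, were tested with limma's camera on 1 probe set per gene, the one with the highest mean, with a preset correlation between genes of 0.01 and adjustment over the lists. Camera was repeated with a correlation estimated from the 6 arrays, and limma's fry was run, which asks whether the genes of a set move one way on balance and does not compare the set with other genes. A list passing with the preset correlation is called so below with the p from the estimated correlation beside it, because none of the 32 passed with an estimated correlation or with fry. Members of a list were also adjusted over the list alone. The words rose and fell are used for genes that passed over all probe sets or adjusted over the list alone. For lists that passed camera with the preset correlation they give the direction of that call only. Among these lists the estimated correlation ran from 0.0071 for Wnt, Notch and hedgehog targets to 0.85 for G2 and M phase. It was 0.76 for G1 and S phase, 0.52 for alveolar type I cells and 0.15 for glucocorticoid targets. Where genes are correlated beyond 0.01, the p with the preset correlation is too small.

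The rule for named genes took Carm1, Gadd45g and Scn3a. Per direction it took the 15 genes of largest log2 difference among those past the adjusted threshold with no overlap between the groups, or, where fewer than 5 passed, the 10 of smallest p with no overlap. From each list it took up to 4 members past the adjusted threshold over all probe sets, and otherwise the 2 of smallest p. List members named beyond these, to spell out a short count or as familiar markers, were chosen after their values were seen. Where a gene had several tested probe sets, they were compared.

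The tests were tested on simulated data for this comparison, with 27022 probe sets of which 200 were changed in each of 10 runs. At a change of 1.5-fold 3.88% of the changed probe sets were recovered, at 2-fold 34.3% and at 4-fold 77.9%, with 3.4 false calls per run and 0 calls per run when nothing was changed. For the gene list test, 30 of 30 simulated lists shifted by 0.4 log2 and 0 of 170 unshifted lists were called. The simulated genes were uncorrelated by construction, whereas the estimated correlation of a called list reached 0.85. The simulation therefore gives no rate of false calls for lists of correlated genes.

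The alternatives fixed beforehand were quantile normalization, median centring, offsets of 16 and 64 on the signal, no filter and a 60th percentile filter, eBayes without a trend and with robust variance, array weights, the replicate number as a block, each array left out in turn, and for the lists the mean of a gene's probe sets, an estimated correlation and fry. After the data had been seen, 3 were added: the presence of spike-in RNA as a term, the 4 arrays without spike-in RNA alone, and fetal sex as a term. The median log2 difference over all tested probe sets was 0.0187 in the main setting, −0.00872 after quantile normalization and −0.0405 after median centring. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.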

Results

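Lung RNA from mice lacking Carm1, which encodes an arginine methyltransferase that acts as a coactivator of nuclear receptors, was compared with wild-type lung RNA on 6 arrays, 3 per genotype, at embryonic day 18.5 by the study's design. The sample labels of the wild types say neonatal, so an age difference between the genotypes cannot be ruled out from the labels. The median signal of an array lay between 106.2 and 121.5, and correlations between arrays were between 0.937 and 0.969, with no 2 arrays alike enough to be 1 sample deposited under 2 names. The arrays did not separate by genotype overall: the highest correlation was between wild type replicate 2 and knockout replicate 1, above every pair within a genotype. On the first principal component, with 33.1% of the variance, wild type replicate 2 (29.7) lay with knockout replicates 1 and 3 (54.0 and 18.3), and knockout replicate 2 (−14.6) lay on the side of wild type replicates 1 and 3 (−41.1 and −46.3). The transcripts of the Y chromosome and Xist marked wild type replicate 3 and knockout replicate 2 as male and the other 4 arrays as female. Control probe sets for bacterial RNA that can be added before labelling had a median signal of 609 on wild type replicate 1 and 379 on wild type replicate 3, against 4.29 on wild type replicate 2 and 6.94, 11.3 and 11.4 on knockout replicates 1 to 3. Bacterial RNA was thus present on 2 of the 3 wild-type arrays and on no knockout array, and whether any other step of their handling differed is not known here. Among the 4 arrays without it, only wild type replicate 2 could be set against the knockouts, and values from that comparison are given below as values without spike-in RNA.

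**Figure D1:**
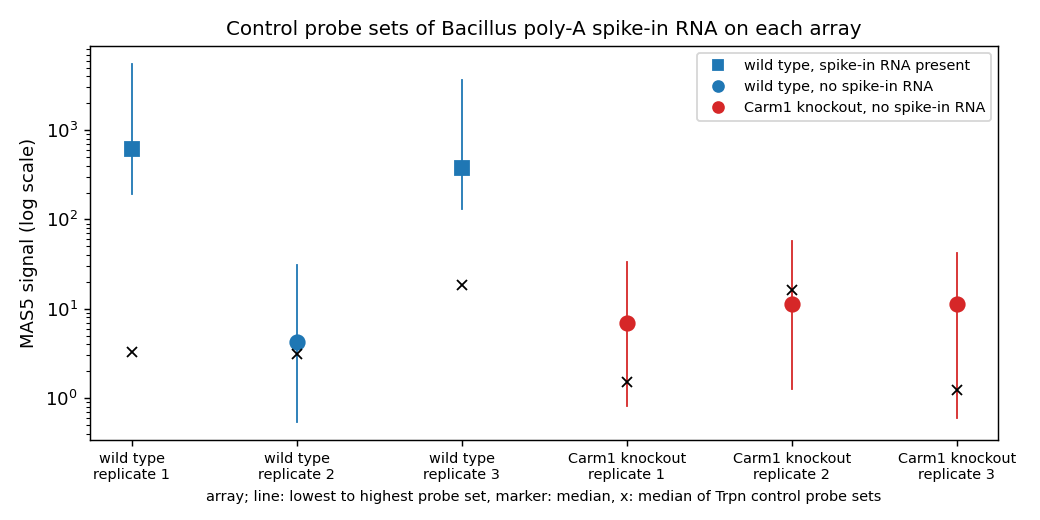
MAS5 signal (log scale) of the control probe sets for bacterial spike-in RNA on each of the 6 arrays, with the median as a marker, the lowest to highest probe set as a line and the median of tryptophan-gene control probe sets as a cross. The medians of wild type replicates 1 and 3, at 609 and 379, stand above the other 4 arrays, which lie between 4.29 and 11.4.

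The signal of the targeted gene was lower in the knockout lungs. Carm1, measured by 1 probe set that may cross-hybridise, had a signal of 786 ± 96.4 (SD, n = 3) in wild type and 427 ± 73.6 in knockout. The knockout level was 54.0% of the wild-type level, with a 95% confidence interval from 41.7% to 70.0%, and all 3 knockout arrays lay below all 3 wild-type arrays. Its adjusted p over all probe sets was 0.105, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give. Where this probe set lies relative to the deleted part of the gene is not known here, so its level checks the labels only in part and does not show how much intact transcript remained. Among the 4 arrays without spike-in RNA the difference was −0.68 on the log2 scale, against −0.89 over all arrays.

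Over all probe sets, the genes that fell in knockout lung were Cyp2e1, Xdh, Scn3b, Zbtb16, Spon1 and Ndnf. The 1 gene that rose past the same threshold was Crabp1. Cyp2e1, a cytochrome P450 of xenobiotic metabolism, went from 881 ± 252 to 187 ± 40.9, 4.66-fold lower (log2 −2.22, SE 0.24, adjusted p = 0.0287). Xdh, encoding xanthine dehydrogenase of purine breakdown, went from 992 ± 130 to 265 ± 84.5, 3.84-fold lower (adjusted p = 0.0404). Scn3b, a beta subunit of voltage-gated sodium channels, went from 2135 ± 324 to 740.2 ± 89.9, 2.87-fold lower. Zbtb16, a zinc finger transcription factor induced by glucocorticoids, went from 1591 ± 118 to 640.3 ± 83.5, 2.49-fold lower. Spon1, a secreted matrix protein, was 2.20-fold lower and Ndnf, a secreted neuron-derived neurotrophic factor, fell from 7397 ± 399.6 to 3499 ± 227, or 2.12-fold. Scn3b, Zbtb16, Spon1 and Ndnf each had an adjusted p of 0.0265. Crabp1, a cytoplasmic retinoic acid binding protein, went from 120.3 ± 11.7 to 727 ± 307, 5.74-fold higher (log2 2.52, SE 0.27, adjusted p = 0.0287). All 7 genes had 3 of 3 knockout arrays beyond the wild-type range.

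With limma 8 of 27022 probe sets passed the adjusted p, 1 higher and 7 lower, and 1 of the lower probe sets had no single gene symbol. At an unadjusted p under 0.05 there were 3683, where chance gives 1351. The second count, at a p under 0.01 and at least 1 log2 unit, held 208 probe sets, 111 higher and 97 lower, and a p under 0.01 alone held 1171 where chance gives 270. In 5413 probe sets, 20% of those tested, the groups did not overlap, where chance gives 10%. Of the named genes with several tested probe sets, Scn3b (2), Ndnf (2), Zbtb16 (3) and Spon1 (4) had 1 past the threshold each and the others lower without passing. The count of 8 was fragile: it became 0 when wild type replicate 1, wild type replicate 3, knockout replicate 2 or knockout replicate 3 was left out, 2 without wild type replicate 2 and 13 without knockout replicate 1. Without an intensity trend in eBayes it was 0, with robust variance 40, and with sex as a term 4, where Crabp1, Zbtb16 and Xdh no longer passed. With spike-in RNA as a term 2 probe sets passed, none of them among the 8, although the differences of the 7 genes without spike-in RNA kept their direction, from −2.65 for Cyp2e1 to 2.38 for Crabp1.

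**Figure D2:**
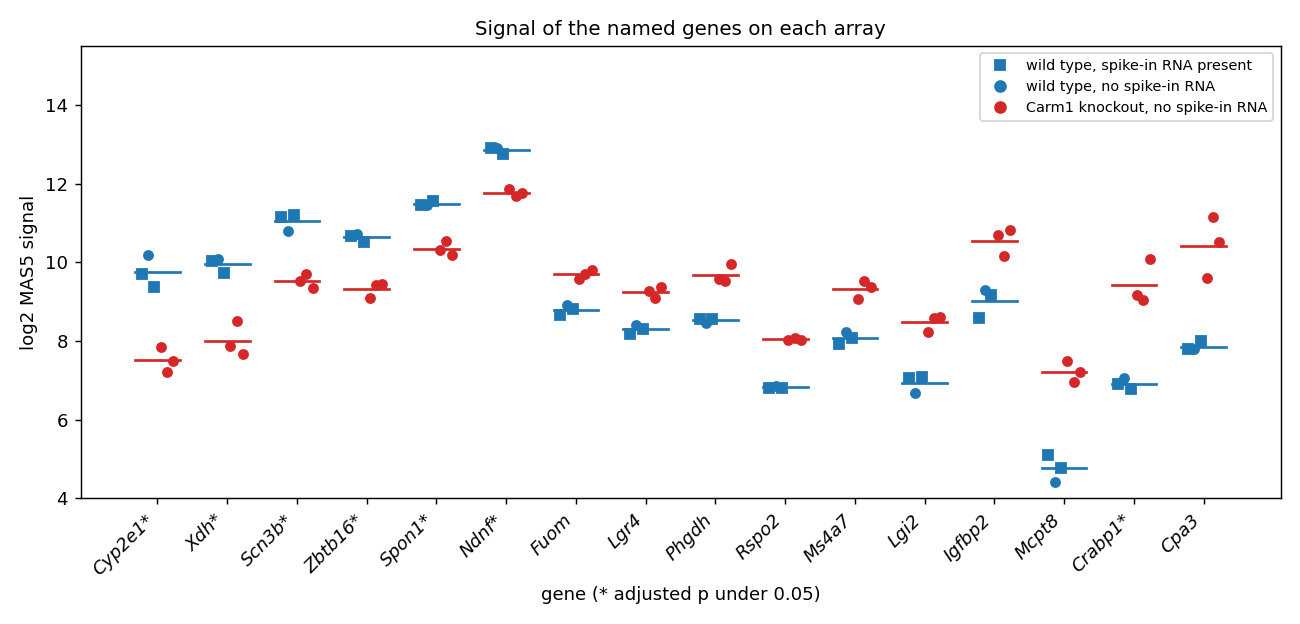
Log2 MAS5 signal on each of the 6 arrays for the 6 genes that fell past the adjusted p over all probe sets and for Crabp1. Also shown are the 9 next genes of smallest p in the higher direction with no overlap between the groups. Group means are lines, colour gives genotype and squares mark arrays with spike-in RNA. In every gene shown the 3 knockout arrays lie on 1 side of the 3 wild-type arrays, which the rule for named genes required. Differences run from Cyp2e1 at −2.22 to Cpa3 at 2.57 log2, and the 7 genes with an asterisk passed the adjusted p.

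Besides Crabp1, the genes of smallest p in the higher direction did not pass the adjusted threshold, with adjusted p between 0.0796 and 0.0909. Signals of the mast cell carboxypeptidase Cpa3 averaged 232 ± 19.9 in wild type and 1508 ± 759 in knockout, and those of Mcpt8, a protease of basophils, 27.6 ± 6.56 and 151 ± 29.2. For Igfbp2, an insulin-like growth factor binding protein, the means were 526 ± 128 and 1528 ± 345, and for Ms4a7, a macrophage membrane protein, 271 ± 29.2 and 645 ± 102. Phgdh, the first enzyme of serine synthesis, was measured at 368 ± 13.6 and 833 ± 139, or 2.24-fold, at the probe set of smallest p, and its other 3 probe sets differed by 1.64-fold, 1.31-fold and 1.31-fold. All 4 may cross-hybridise. Rspo2, a ligand that enhances Wnt signalling, was at 113 ± 2.30 and 264.5 ± 6.46, and Lgr4, a receptor of R-spondins, at 316 ± 23.1 and 609.8 ± 57.2. The remaining 2, Lgi2 and Fuom, differed by 2.89-fold and 1.86-fold, and the second probe set of Lgi2 by 1.60-fold. For Gadd45g, a growth arrest and DNA damage gene, the means were 1916 ± 576 and 1211 ± 117 (log2 −0.62, SE 0.20, adjusted p = 0.238), and for the sodium channel Scn3a 120 ± 17.1 and 89.8 ± 24.4 (adjusted p = 0.575), neither past the threshold. Among the 4 arrays without spike-in RNA the difference of Gadd45g was −0.23, and it was −0.40 without wild type replicate 1 and −0.82 without wild type replicate 2. The difference of Scn3a was −0.44 over all arrays, −0.19 without knockout replicate 3 and −0.23 without spike-in RNA.

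Markers of the alveolar type I cell, the flat cell of gas exchange, fell as a group in knockout lung. Of 18 measured members 16 were lower and 2 higher, with a median log2 difference of −0.57, and 15 passed when adjusted over the list alone while 0 passed over all probe sets. Aqp5, a water channel, fell from 2441 ± 840.5 to 746 ± 252, Emp2 from 18278 ± 2746 to 10445 ± 1199, and the lung claudin Cldn18 and the receptor Ager by 0.65 and 0.55 on the log2 scale. The 2 members that rose adjusted over the list alone were Igfbp2, an insulin-like growth factor binding protein, and Cyp2b10, a cytochrome P450. The list passed camera with the preset correlation (adjusted p = 9.17e-10), but not with an estimated correlation (adjusted p = 0.421). The array means of the knockouts were −0.14, −0.04 and −0.53, lowest on knockout replicate 3. That array was also lowest for the type II, ion transport, fatty acid synthesis, glucocorticoid (−0.28) and endothelial (−0.28) lists below. Without that array the type I median was −0.45, and without spike-in RNA it was −0.55.

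Markers of the alveolar type II cell, which makes surfactant, were lower as well. The list had 16 of 18 members lower with a median of −0.25, which was −0.16 without wild type replicate 1 or without knockout replicate 3, and 4 members fell adjusted over the list alone, namely the complement gene Hc (4993 ± 876 to 2545 ± 792), the lung chemokine Cxcl15, Muc1 and the phosphate transporter Slc34a2. Sftpc, the surfactant protein C gene, was at 50143 ± 6509 in wild type and 52420 ± 3618 in knockout, and Sftpb at 17452 ± 4124 and 17746 ± 3373, and these were the 2 members that were higher. Sftpa1 was at 18750 ± 4608 and 14232 ± 1931 and Sftpd at 10804 ± 1589 and 10207 ± 2005, and none of the 4 surfactant protein genes passed adjusted over the list alone. Sftpc lay at the top of the signal range, where an array may not resolve a difference. The list passed with the preset correlation (adjusted p = 1.67e-05) and not with an estimated correlation (adjusted p = 0.421). Ion and fluid transport genes were lower in 10 of 11, with a median of −0.44, which was −0.19 without knockout replicate 3. The members Aqp1, Aqp5 and the epithelial sodium channel subunits Scnn1a (1383 ± 113 to 598 ± 246) and Scnn1g fell adjusted over the list alone. That list had an adjusted p of 5.11e-05 with the preset correlation and an adjusted p of 0.421 with an estimated correlation. Genes of fatty acid and phospholipid synthesis were lower in 15 of 20 with a median of −0.20, which was −0.12 without knockout replicate 3. Of these Fasn, Chka, Scd2, Scd1 (17485 ± 2775 to 8626 ± 3810.4) and Lpin1 fell adjusted over the list alone. Further probe sets of Chka differed by only −0.14 and −0.076 on the log2 scale. The fatty acid list had an adjusted p of 1.18e-04 with the preset correlation and an adjusted p of 0.421 with an estimated correlation. Cholesterol synthesis genes did not pass (16 members, adjusted p = 0.996), and their median of 0.077 and the direction of the test differed in sign. The median itself went from −0.097 without knockout replicate 1 to 0.17 without knockout replicate 3. Among the 4 arrays without spike-in RNA the medians were −0.20 for type II cells, −0.23 for ion and fluid transport and −0.19 for fatty acid synthesis.

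Targets of glucocorticoids, the hormones that mature the lung before birth, fell together. Of 19 members 15 were lower, with a median of −0.46, and 13 fell adjusted over the list alone, of which Zbtb16 also passed over all probe sets. Examples were Tsc22d3 (4375 ± 350.3 to 2452 ± 323), Klf9 (6095 ± 466 to 3053 ± 732) and the receptor chaperone Fkbp5 (1584 ± 131 to 873 ± 153). The receptor gene itself, Nr3c1, was at 3046 ± 318 and 2882 ± 637 and did not pass. The list had an adjusted p of 1.51e-09 with the preset correlation and an adjusted p of 0.300 with an estimated correlation, and its median without spike-in RNA was −0.41. Targets of p53 and the Gadd45 family were lower in 14 of 17 with a median of −0.24, which was −0.16 without wild type replicate 1 and −0.14 without knockout replicate 1. Adjusted over the list alone 2 fell, Trp53inp1 and the death receptor Fas. The 3 higher members were Gadd45a (477 ± 53.9 and 651 ± 74.3), Mdm2 and Sesn2. Gadd45g and Gadd45b were lower, at −0.62 and −0.25 on the log2 scale. Neither of them nor Gadd45a passed adjusted over the list alone. That list passed with the preset correlation (adjusted p = 0.00380), not with an estimated correlation (adjusted p = 0.339), and not with spike-in RNA as a term, where its median was −0.13.

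Cell cycle genes rose in knockout lung. All 20 measured genes of G1 and S phase were higher, with a median of 0.59, and 17 rose adjusted over the list alone, among them the replication helicase subunit Mcm5 (1182 ± 157 to 2231 ± 463) and Uhrf1 (438 ± 102 to 778 ± 58.7). All 23 genes of G2 and M phase were higher as well, with a median of 0.61, and 15 rose adjusted over the list alone, including Mki67, the kinesin Cenpe and the survivin gene Birc5. The adjusted p values with the preset correlation were 5.55e-12 and 4.79e-09, and the adjusted p with an estimated correlation was 0.421 for both. On the array means, the 3 knockout arrays lay above the 3 wild-type arrays for G1 and S phase, but for G2 and M phase knockout replicate 2 at −0.12 lay within the wild-type range. The medians without spike-in RNA were 0.57 and 0.43. Of 12 cyclin-dependent kinase inhibitors, D cyclins and retinoblastoma family genes, the inhibitors Cdkn2b (1581 ± 388 to 682 ± 179) and Cdkn1b fell and the inhibitor Cdkn2c rose adjusted over the list alone, and the list did not pass (adjusted p = 0.996). At the second probe set of Cdkn1b the difference was −0.22 on the log2 scale and the groups overlapped.

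**Figure D3:**
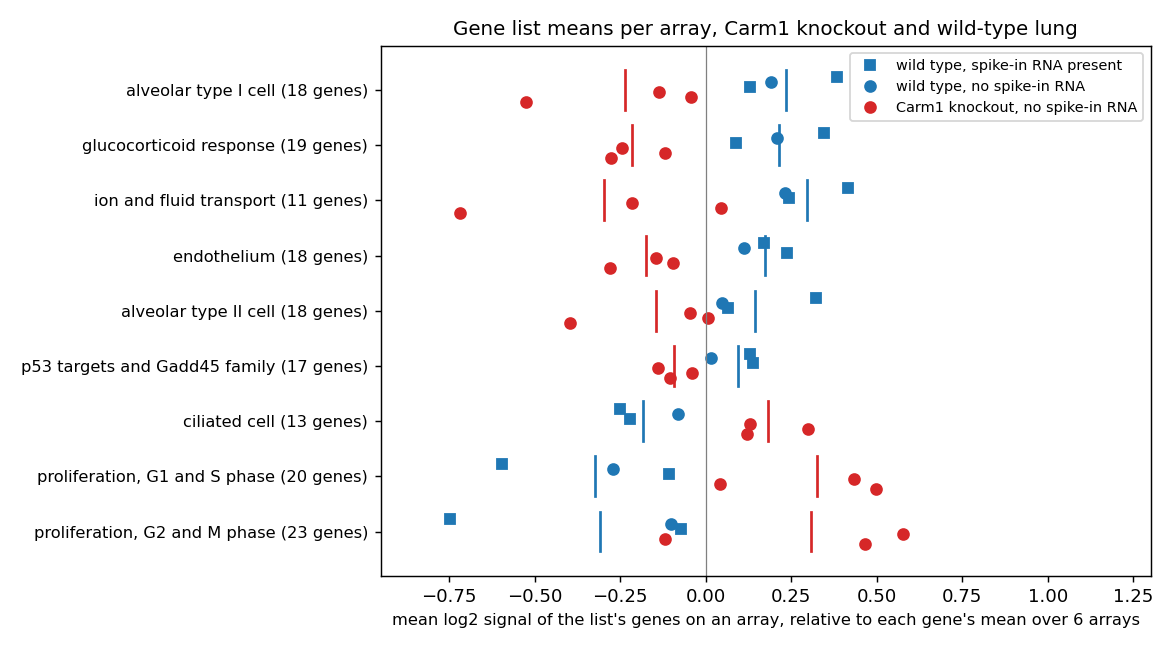
Mean log2 signal of each list's genes on each of the 6 arrays, relative to each gene's mean over the arrays, for 9 gene lists, with group means as lines, colour for genotype and squares for the 2 arrays with spike-in RNA. The 3 knockout arrays lie on 1 side of the 3 wild-type arrays in every list shown except G2 and M phase. There knockout replicate 2 is at −0.12. Of the called lists not shown, fatty acid synthesis and Wnt, Notch and hedgehog targets separated as well. The distal tip, erythroid, macrophage, cardiac, interferon and circadian lists, also called, did not separate.

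Endothelial markers fell, with 15 of 18 lower and a median of −0.30. The 8 members that fell adjusted over the list alone were led by Car4, a carbonic anhydrase of lung capillaries (742 ± 130 to 185 ± 73.5), and included the adrenomedullin receptor component Ramp2 and the vascular growth factor receptor Kdr. The list had an adjusted p of 3.44e-06 with the preset correlation and an adjusted p of 0.300 with an estimated correlation, and its median without spike-in RNA was −0.21. Fibroblast and matrix genes went both ways and did not pass as a list (17 members, 9 higher and 8 lower, adjusted p = 0.996). Elastin (Eln) fell from 19013 ± 2212 to 11609 ± 1372 and Fn1 fell by 0.34 on the log2 scale, while the proteoglycans Lum and Dcn and the collagen Col1a1 rose, all adjusted over the list alone. Smooth muscle and pericyte genes did not pass (12 members, adjusted p = 0.664), although their member Hhip, an inhibitor of hedgehog signalling, fell from 2833 ± 390.2 to 1276 ± 254 adjusted over the list alone. Actg2, of smooth muscle, had means of 530 ± 68.8 and 702 ± 102. Targets of Wnt, Notch and hedgehog were lower in 8 of 13 with a median of −0.17 (adjusted p = 0.0291 with the preset correlation, adjusted p = 0.421 with an estimated correlation), and Hhip, the Notch target Hey1 and Nkd1 fell adjusted over the list alone. The call of that list ended, at adjusted p between 0.0585 and 0.0711, without wild type replicate 1 (median −0.088), wild type replicate 2 (−0.044) or knockout replicate 1 (−0.25).

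Ciliated cell markers were higher in all 13 members, with a median of 0.30, which was 0.49 without wild type replicate 2, and 5 rose adjusted over the list alone, namely Tubb4b, Tekt1, Rsph1, Ccdc113 and Cfap206. Tubb4b went from 5883 ± 835 to 9216 ± 313, but 1 of its 2 tested probe sets had the opposite sign. Foxj1, the master regulator of motile cilia, had means of 707 ± 88.5 and 777 ± 184 and did not pass. The list had an adjusted p of 6.71e-04 with the preset correlation and an adjusted p of 0.300 with an estimated correlation, and its median without spike-in RNA was 0.20. Club cell genes did not pass (12 members, 8 higher and 4 lower, median 0.10, adjusted p = 0.20), with the 3 knockout array means above the 3 wild-type means, and the list passed without wild type replicate 1 (median 0.26, adjusted p = 0.0211), while its median was 0.0091 without wild type replicate 3. Krt15, a keratin of airway epithelium, rose from 921 ± 276 to 3616 ± 1850 adjusted over the list alone. The secretoglobin Scgb3a1 was at 4101 ± 6098 and 17713 ± 18383, a spread wider than the difference. Neuroendocrine genes did not pass (6 members, median 0.50, adjusted p = 0.225). There Grp had means of 329 ± 28.8 and 498 ± 99.6, and Scg2 41.9 ± 35.04 and 166 ± 145. Distal tip progenitor genes were lower in 11 of 15 with a median of −0.08, and Shh fell from 6672 ± 265 to 4815 ± 404 adjusted over the list alone. For Mycn, whose 3 probe sets differed in sign, the means were 508 ± 56.7 and 360.3 ± 10.98. The distal tip call (adjusted p = 0.0133, and adjusted p = 0.421 with an estimated correlation) ended without wild type replicate 3, at a median of −0.051, and with spike-in RNA as a term, where the median was 0.0063. Its median was −0.13 without wild type replicate 2, −0.15 without knockout replicate 2 and −0.16 without knockout replicate 3.

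Array means of blood and cardiac muscle lists differed widely within a genotype. Erythroid genes had a median of 1.29 with 10 of 11 higher, and Hbb-y, an embryonic globin, went from 727 ± 570.1 to 5588 ± 4875, the 1 member past the list alone. Hbb-bh1 was at 105.5 ± 24.1 and 311 ± 194. Without spike-in RNA the log2 differences of Hbb-y and Hbb-bh1 were 1.67 and 1.06, against 2.88 and 1.40 over all arrays. In that comparison these 2 members were the only higher ones and 9 were lower. The erythroid list passed with the preset correlation (adjusted p = 0.0134) and not with an estimated correlation (adjusted p = 0.605), but its array means were 0.74 on wild type replicate 2 and 1.90 on knockout replicate 1, and its median without spike-in RNA was −0.37. Without knockout replicate 1 the median was 0.49 and the adjusted p 0.204, without wild type replicate 1 it was 0.231 and without wild type replicate 3 it was 0.0846. Macrophage and leukocyte genes were higher in 15 of 19 with a median of 0.25 (adjusted p = 0.0478, and adjusted p = 0.610 with an estimated correlation) and a median without spike-in RNA of −0.012. Leaving out knockout replicate 1 (median 0.13), wild type replicate 1 (0.26) or wild type replicate 3 (0.16) ended that call, and the median was 0.40 without wild type replicate 2 and 0.49 without knockout replicate 3. C1qa had means of 816 ± 102 and 1153 ± 145 and Aif1 165 ± 51.0 and 288 ± 23.3. Cardiac muscle genes were higher in all 10 with a median of 0.89 and 0 past the list alone (adjusted p = 0.00443, and adjusted p = 0.511 with an estimated correlation), and the array means reached 1.40 on knockout replicate 2. That call ended without wild type replicate 3 (median 0.41) or knockout replicate 2 (0.42), and the median without spike-in RNA was 0.28. Actc1 was at 3194 ± 1803 and 9114 ± 4734, and Myh7 at 1142 ± 22.6 and 1403 ± 126.

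Liver, skeletal muscle, squamous and mesothelial genes did not pass in the main setting, but each passed in some of the others. Liver genes, with a median of 1.73 (adjusted p = 0.241), were high on wild type replicate 2 and knockout replicate 1, at array means of 3.93 and 4.53, and low on wild type replicate 3 at −5.67. The median was −0.58 without wild type replicate 3 and −0.094 without knockout replicate 1. That list passed without wild type replicate 2 (median 4.25) or knockout replicate 2 (3.17). With spike-in RNA as a term and in the 4 arrays without it the median was −2.90, in the opposite direction. Both of these settings compare the knockouts with wild type replicate 2 alone, where liver genes were high. Afp had means of 9951 ± 16257 and 15026 ± 17105, and Ttr 7345 ± 12183 and 13067 ± 20325. Skeletal muscle genes (median 1.46, adjusted p = 0.0604) had an array mean of 4.43 on knockout replicate 3 and a median of −0.44 without that array, 2.44 without knockout replicate 1 and −0.32 without spike-in RNA. In this list Ckm was at 417 ± 338 and 1748 ± 1756, with Tnnt1 at 218 ± 90.3 and 686 ± 521. Squamous genes (5 members, median 0.78, adjusted p = 0.0857) were also highest there, at 1.54, with a median of 0.30 without that array, and Sox2 and Krt4 rose adjusted over the list alone. The Krt4 difference was 1.68 on the log2 scale and 0.965 without that array, and the groups overlapped at its second probe set. The mesothelial list (7 members, median −0.20, adjusted p = 0.0625) passed without wild type replicate 1 (median −0.50) or knockout replicate 2 (−0.45), and its median was −0.066 without knockout replicate 1. Its member Msln fell from 3927 ± 723 to 2387 ± 481 adjusted over the list alone and Upk3b had means of 3015 ± 749.8 and 2046 ± 502. For thymus, adipocytes and sex too few genes were measured for a list test. Of these Cd8a was at 114 ± 36.7 and 61.3 ± 29.3, Fabp4 at 1165 ± 359.6 and 2132 ± 814, Cd36 at 8457 ± 544 and 6859 ± 957, and Xist at 8245 ± 7124 and 7800 ± 6713.

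Among stress and signalling lists, interferon response genes were lower in 8 of 10 with a median of −0.58 and 0 past the list alone (adjusted p = 0.0169, and adjusted p = 0.561 with an estimated correlation). Rsad2 had means of 1401 ± 847 and 595 ± 153 and Usp18 781 ± 86.5 and 488 ± 208. That call ended without wild type replicate 1, knockout replicate 1 (median −0.25) or knockout replicate 3 and with spike-in RNA as a term, where the median was −0.45. Circadian clock genes had a median of −0.16 with 7 of 12 lower (adjusted p = 0.0352, and adjusted p = 0.421 with an estimated correlation). Of these Tef fell from 2104 ± 157 to 1407 ± 131 adjusted over the list alone, with 1 of its 3 probe sets of the opposite sign, and Per2 had means of 662 ± 54.7 and 429 ± 111. The circadian call ended without wild type replicate 3 (median −0.061) or knockout replicate 1 (−0.097) and with spike-in RNA as a term, where the median was −0.20. Its median was −0.068 without knockout replicate 3. Immediate early and heat shock genes did not pass (13 members, adjusted p = 0.119), though Jun (3665 ± 231 to 2529 ± 110.3), Fos and Zfp36 fell adjusted over the list alone. Hypoxia genes did not pass (15 members, adjusted p = 0.288). Among them Tpi1 had means of 6802 ± 1387 and 9921 ± 1722 and Pgk1 5652 ± 1167 and 7643 ± 935. Targets of retinoic acid and TGF-beta did not pass (9 members, adjusted p = 0.138), although the 3 knockout array means lay below the 3 wild-type means, with Ccn2 down from 3902 ± 575 to 2318 ± 316 adjusted over the list alone and Tgfbi at 3828 ± 244 and 3049 ± 382. Of the 15 arginine methyltransferases and partners of CARM1 only Carm1 passed adjusted over the list alone, Prmt2 was at 1778 ± 128 and 1446 ± 91.0, and the list did not pass (adjusted p = 0.771).

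Genes near Carm1 on chromosome 9 did not pass as a list. The 27 measured neighbours had a median of 0.0061 (−0.0012 to 0.048 with 1 array left out), 15 higher and 12 lower, with 0 past the list alone (adjusted p = 0.996), and the direction of the test was opposite in sign to the median. Their mean difference was 0.093, and the array means of the knockouts (0.073, 0.023 and 0.043) lay above those of the wild types (−0.022, −0.062 and −0.055). In fry, the unadjusted p for change in either direction was 0.0176. Other lists that did not pass had a smaller one, such as fibroblast and matrix genes at 0.0085, so it does not set the neighbours apart. Of the neighbours, Cnn1 had means of 89.7 ± 22.6 and 234 ± 136 and Rab3d 1140 ± 59.0 and 907 ± 44.3. Of cholesterol synthesis genes, Dhcr7 was at 244 ± 30.9 and 365 ± 60.3 and Srebf2, whose 2 probe sets differed in sign, at 741 ± 107 and 579 ± 76.2.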

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

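The comparison of cartilage genes, the test on chromosome 9 and those of a preparation marked by spike-in RNA were set before their results were seen, and the test of epithelial share, the count over other splits, the criterion for the 7 called genes on chromosome 9 and the added lists were chosen afterwards. The limit for the share of chromosome 9 genes was first read without its spread and then with it, which left that test undecided.

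The control probe sets for bacterial RNA carried signal on 2 arrays, with medians of 609.5 on wild type replicate 1 and 378.5 on wild type replicate 3, while the other 4 arrays stood between 4.29 and 11.4. This signal lies outside the measured transcripts. Whether those 2 wild-type arrays were also prepared or hybridised apart from the others is not known here.

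The fall of alveolar type I and glucocorticoid genes and the rise of cell cycle genes could come from a preparation that goes with the spike-in RNA, from an admixture of other tissue, from a younger or less mature knockout lung, or from loss of Carm1. If such a preparation were the cause, wild type replicate 2, which like the knockouts had no spike-in RNA, would lie near them, but the median difference of knockout minus that array was −0.5464 for alveolar type I genes, −0.4121 for glucocorticoid targets, 0.5662 for G1 and S phase and 0.4256 for G2 and M phase. Over all probe sets, however, wild type replicate 2 did lie nearest to a knockout array, at a correlation of 0.969 with knockout replicate 1. These arrays also had the highest liver means (3.93 and 4.53) and erythroid means (0.74 and 1.90). Knockout replicate 2, without spike-in RNA, correlated at 0.965 with wild type replicate 3, which had it, and at 0.955 with wild type replicate 2. The nearness is thus no clear sign of a shared preparation. The 4 medians are near the pooled medians of −0.57, −0.46, 0.59 and 0.61, except G2 and M phase, where knockout replicate 2 lay within the wild-type range, but 1 array has no spread, so preparation and genotype cannot be told apart here. Admixture of tissue without lung epithelium, acting alone, would lower all epithelial markers alike. The ciliated median, however, exceeded the alveolar type I median by 0.8618 with quartile ranges that did not meet. That test was chosen after both lists had been seen. A separate rise of ciliated genes beside such admixture would give the same result, so the test does not exclude it. Nor does it cover admixed airway tissue, which would raise ciliated genes while lowering alveolar ones. Knockout replicate 3 was lowest for alveolar type I genes (−0.525) and highest for skeletal muscle (4.43) and cartilage (2.17), and without it the alveolar type I median was −0.4471, with the alveolar type I and ciliated lists both still called. Admixed airway tissue was not tested as a cause of the alveolar fall and stays open. The age of the lungs, labelled neonatal in wild type and embryonic day 18.5 in knockout, was not tested and stays open, as does loss of Carm1.

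Of the 7 genes called, 3 lie on chromosome 9 with Carm1, namely Scn3b, Zbtb16 and Crabp1 (Fisher's exact p = 0.00511, a criterion seen first in the data). DNA of the strain of the targeted cells may have stayed linked to the knockout allele. Among the 94 genes with an adjusted p under 0.10, 7.45% lay on chromosome 9 (exact 95% interval 3.05% to 14.7%), against 5.58% of the 12925 genes with a chromosome (Fisher's exact p = 0.368), and the interval reached beyond the limit of 8.37% set for excluding this, so it stays open. Between Carm1 and Scn3b, Zbtb16 and Crabp1 stood 80, 145 and 186 tested genes. Of those 186, 26.3% had a p under 0.05 at their probe set of smallest p, against 21.0% of all genes. The 27 measured genes of the list written as near Carm1, which were not ranked by distance, had a median of 0.0061. Their 3 knockout array means lay above the 3 wild-type means. No sequence or strain information was used here.

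Ciliated cell genes were higher in knockout lung, while club cell genes did not pass as a list. The ciliated difference could reflect more cartilaginous airway in the dissected pieces. Cartilage genes (11 measured, chosen after the data had been seen) had a median of 0.6144, but the array means were 2.17 on knockout replicate 3, 0.19 on knockout replicate 2 and −1.002 on knockout replicate 1, below all wild types, so the test did not decide. Ciliated means on the same arrays were 0.12, 0.30 and 0.13, and thus did not follow the cartilage means among the knockouts. The skeletal muscle and squamous lists stood out on the same knockout replicate 3.

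For the count of 8 probe sets, 1 of the 10 splits of the 6 arrays into 3 and 3 gave as many, the real one, and the highest of the others gave 0. At an unadjusted p under 0.05 the real split gave 3683 and the highest other 1533. With 10 splits the share cannot go below 0.1.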

How the results depend on the processing

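Spike-in RNA as a term, the 4 arrays without spike-in RNA and sex as a term were chosen after the data had been seen. Against 8 probe sets past the threshold, 1 higher and 7 lower, median centring gave 2 higher, eBayes without trend 0 (0 higher, 0 lower), robust variance 40 (10 and 30), sex as a term 4 (0 and 4), spike-in RNA as a term 2 (2 and 0) and the 4 arrays 3 (2 and 1), none of the last 2 settings sharing a probe set with the 8. The replicate block, which paired arrays of the same number, gave 0 (0 higher, 0 lower). Deviations of same-numbered arrays correlated at −0.14, −0.38 and −0.0056, so these values gave no sign of pairing by number. Other differences between the arrays could hide a pairing, which is therefore not excluded. Leaving out 1 array gave 0 to 13 in total, 0 to 4 higher and 0 to 9 lower. The second count of 208 became 97 with an offset of 64, 372 without a filter and 113 with the 60th percentile filter. Quantile normalization, the offsets, both filters and array weights kept the count of 8 within 1.5 times. Of 82 named genes, the 7 called lost their calls without trend, with the block, in both spike-in settings and without wild type replicate 1 or 3 or knockout replicate 2 or 3. Of the 7, 6 lost theirs without wild type replicate 2, 3 with sex as a term, and 1 each with array weights and without knockout replicate 1. Among the others 10 gained a call with robust variance, 2 with median centring and 2 without knockout replicate 1. Leaving out 1 array moved the difference of 18 named genes more than 1.5 times, and 2 of them, Ttr and Xist, changed sign. The difference of Carm1 ranged from −1.03 to −0.68 and never passed. Except where fewer samples or genes entered, the cause was not tested.

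Of 32 lists 17 passed in the main setting, 12 to 19 with 1 array left out, 11 with spike-in RNA as a term and 11 with the 4 arrays (10 shared each), and 0 with an estimated correlation and 0 with fry. Those 2 tests ended all 17 calls at unchanged medians: G1 and S phase 0.59, G2 and M phase 0.61, type I −0.57, type II −0.25, glucocorticoid −0.46, endothelium −0.30, ion transport −0.44, fatty acid −0.20, ciliated 0.30, p53 −0.24, cardiac 0.89, distal tip −0.082, erythroid 1.29, interferon −0.58, Wnt −0.17, circadian −0.16 and macrophage 0.25. The first 9 held their calls in every other setting run. All of those settings kept the preset correlation of 0.01, so they do not test that assumption. Among these, the 2 spike-in settings both compare the knockouts with wild type replicate 2 alone, so they are 1 comparison without spread and add no support. Leaving out 1 array moved the medians of some (type II to −0.16, ion transport to −0.19, fatty acid to −0.12, ciliated to 0.49), as it did for p53 (to −0.14). With spike-in RNA as a term and in the 4 arrays alike, medians of lists that lost their call were −0.13 for p53, 0.28 for cardiac, 0.0063 for distal tip, −0.45 for interferon and −0.20 for circadian, while erythroid (−0.37), macrophage (−0.012) and liver (−2.90) reversed. Of the lists not called, skeletal muscle passed in 9 settings, mesothelium in 6, liver in 4 (2 of them reversed), squamous in 3, immediate early in 2, and club cell and hypoxia in 1 each. The mean of a gene's probe sets ended the distal tip (−0.13) and circadian (−0.057) calls, the 60th percentile filter the erythroid call (0.99) and array weights the interferon call (−0.49). With 1 array left out, medians ranged from −0.16 to −0.051 for distal tip, 0.13 to 0.49 for macrophage, 0.49 to 1.72 for erythroid, 0.41 to 1.24 for cardiac, −0.25 to −0.044 for Wnt, −0.79 to −0.25 for interferon and −0.19 to −0.061 for circadian. An offset of 64 shrinks the differences of dim probe sets by construction, and how far their signals lie above background was not tested.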

Other observations

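The lists and genes of this part were chosen after the data had been seen.

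Some mast cell and basophil genes were among the higher genes. In a list written after Cpa3 and Mcpt8 had been seen, so that its count is no independent test, 9 of 11 measured members were higher, with a median of 0.55, and 4 passed adjusted over the list alone. Beside Cpa3 and Mcpt8 these were the chymase Cma1, at 216 ± 9.09 in wild type and 913 ± 465 in knockout, and the tryptase Tpsb2, at 141 ± 14.4 and 833 ± 595. The 3 knockout array means (−0.13, 1.05 and 0.46) lay above the 3 wild-type means (−0.45, −0.67 and −0.26), and the median without spike-in RNA was 1.01. Rab27b and Gata2 were lower, at −0.69 and −0.33 on the log2 scale. The genes Hdc and Kit, also in that list, had means of 2221 ± 561 and 2387 ± 375 for Hdc and 1001 ± 299.6 and 1140 ± 95.5 for Kit.

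Several further genes were lower without passing the adjusted p. Of the collagen genes, Col4a3 was at 836 ± 180.0 in wild type and 271 ± 69.5 in knockout, and Col4a4 at 3649 ± 231 and 1413 ± 371, with each of the 2 and 3 tested probe sets of these genes lower. Angiotensin-converting enzyme (Ace) had means of 788 ± 168 and 316 ± 34.5, the semaphorin Sema7a 973 ± 196 and 400.3 ± 62.7, and the cytochrome Cyp4b1 2192 ± 492 and 850.5 ± 140. Their adjusted p was 0.0852 each. On the higher side, Vcan, Brca1 and Aspm differed by 2.05-fold, 2.45-fold and 2.75-fold at the probe sets of smallest p, with adjusted p of 0.139, 0.147 and 0.130.

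Genes of airway basal and secretory cells were higher in 12 of 13, with a median of 1.40, in a list also written after some of its genes had been seen. Krt15 and Sox2 passed adjusted over the list alone. The array means were −0.97, 0.28 and −1.56 in wild type and 0.19, 0.45 and 1.61 in knockout, so the groups overlapped, and the median without spike-in RNA was 0.34. Of the list's abundant members, Scgb1a1 was at 35579 ± 10836 and 30617 ± 5848 and Scgb3a2 at 44080 ± 6266 and 47260 ± 6577.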
